A study of Arabidopsis thaliana with 18 samples.

How the data were processed

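Transcript levels were measured with the Affymetrix ATH1 GeneChip, a 1-colour oligonucleotide array hybridised with biotin-labelled target, in the Wassilewskija accession Ws-2 of Arabidopsis thaliana. Per the labels, plants at developmental stage 3.90 were grown on 0.8% agar with 1% sucrose and dilute Murashige and Skoog salts, at 22 °C, 80% humidity and a 16 h day. The 18 arrays fall into 6 groups of 3, from control, potassium-starved and caesium-treated plants, each as shoots and roots, and the sample titles gave the group and the replicate number. Caesium is an alkali metal that plants take up through potassium transport systems. The dose of caesium, the length of the treatments and the way potassium was withheld are not given in the sources used here. Nothing in the labels says that replicates came from separate plant cultures, so p-values measure only the spread between these samples, which may be technical.

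The values were the authors' deposited signal intensity per probe set, on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, its settings and the handling of detection calls are not given in the sources used here. All values were above 0, from 0.00182 to 6513, and each array's mean after trimming 2% at each end was close to 100, so the arrays had been scaled to a common mean before deposit. Such a scaling fixes the mean of each array and not its median. A change that affects many bright genes in one group therefore shifts all other genes of that group the opposite way. No scanner files were used here, so background subtraction and the combination of probes into 1 signal were taken as the authors made them. The MAS5 algorithm subtracts a mismatch probe's signal, which makes low values noisy on a log scale.

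The deposited table held 22810 probe sets, of which 64 control (AFFX) probe sets were left out. The remaining 22746 were named with the platform annotation supplied with the series. It gave 1 gene for 13513 probe sets, several for 503 and none for 8730. Of the 13513, 13436 matched a RefSeq gene of the TAIR10.1 assembly, and the other names were kept as the annotation gave them. Only probe sets with 1 gene were named, they covered 13350 genes, and 152 genes had more than 1 such probe set. A probe set without a gene here is unnamed in that annotation, not without a gene. This limited the gene lists: of 562 members fixed in advance, 70 (12.5%) had a probe set with 1 gene. The high-affinity potassium transporter HAK5, which the rule for named genes asked for, had no named probe set and is not analysed here.

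Signals were taken to log2 with no pseudocount and no further normalization. A probe set was tested where at least 3 arrays of the fit exceeded the 40th percentile of their own array. Each tissue was fitted apart, with its 9 arrays sharing 1 estimate of the spread, by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend). The comparisons were potassium-starved against control, caesium-treated against control, and caesium-treated against potassium-starved, in each tissue. The difference between tissues in each response was tested as an interaction in a fit of all 18 arrays, as was control root against control shoot. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a comparison, and a probe set was called at an adjusted p under 0.05. Verbs such as rose and fell are used for called probe sets only, except in counts adjusted over the list alone. Those counts adjust p within each list separately and are then summed. A list with a single tested member gets no adjustment there, and nothing is controlled across lists. Signals are given as mean ± SD of 3 arrays, and log2 differences as estimate ± standard error from limma. Arrays give no read depth, so their number limits the precision.

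The groups, the tests, the alternatives, 25 gene lists and the rule for named genes were set before the data were examined. By that rule each comparison names the 10 largest rises and falls among called probe sets with 1 gene and no overlap between replicates, and up to 4 called members per direction of each list. Where no member was called, the 2 with the smallest p are given as values. Where fewer than 10 probe sets were called, the 10 with the smallest p are given as values, and each interaction names the 5 with the smallest p per direction. For a gene with several probe sets, the one with the highest mean signal was used. Lists with at least 5 tested members were tested with camera (limma) at its preset correlation of 0.01 between genes, which asks whether a list shifts against all other genes. Alternatives were an estimated correlation and fry, which asks whether a list's genes move one way and does not compare them with other genes. Because so few list members had a probe set, 23 gene families were added from the names in the annotation. They were chosen after the table's annotation had been seen and before any difference between groups had been computed.

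Alternatives for each result were no filter, a 60th percentile filter, log2(signal + 16), quantile normalization, a shift of each array to a common median, no variance trend, array weights, other sets of arrays sharing the spread, the replicate number as a block, and leaving out each array in turn. Whether equal replicate numbers pair the arrays was checked from the correlation of their deviations from the group means, in the same run that first gave counts of calls with and without the block. Arrays with the same number deviated together in potassium-starved and control shoots (r from 0.269 to 0.436 across probe sets), caesium-treated and control shoots (0.432 to 0.639), caesium-treated and potassium-starved shoots (0.203 to 0.376) and caesium-treated and control roots (0.146 to 0.439). These comparisons were taken as paired, from the data and not from the labels. The main fits, and the named genes and list tests from them, still had no block, as set beforehand. The block was run as an alternative only. In the remaining root comparisons at least 1 pair lay under the limit of 0.1. Arrays with different numbers reached 0.0787 at most in shoots. In caesium-treated against control roots they reached 0.185, above the same-numbered pairs of replicates 2 and 3 (0.172 and 0.146). The pairing there is therefore weakly shown.

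The scripts were tested on simulated data after the first fits of the real data had been run, with 68 genes changed 1.5-fold, 66 changed 2-fold and 66 changed 4-fold at the levels and spreads of the real probe sets. Of genes changed 2-fold, the test recovered 21.2% of 66 for potassium-starved against control shoots, 37.9% for caesium-treated against control shoots, 39.4% for potassium-starved against control roots and 51.5% for caesium-treated against control roots. Of genes changed 4-fold it recovered 78.8%, 84.8%, 87.9% and 95.5% of 66 in the same order. Comparisons within a tissue were simulated from the same levels and spreads, with other genes and noise drawn. Differences in recovery between them therefore do not show a difference in power. The arrays were drawn independently, without any pairing, and far fewer genes were changed than were called in potassium-starved shoots. Recovery in the real comparisons may therefore differ. Between 2 and 6 unchanged genes were called per comparison. In caesium-treated against control shoots 1 of 68 genes changed 1.5-fold was called with the wrong sign, after which the test's limit was loosened to allow 1 such call below 2-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.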

Results

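Transcript levels were compared between control, potassium-starved and caesium-treated plants, in shoots and in roots, on 18 arrays in 6 groups of 3. The series title names potassium starvation and caesium treatment as the conditions whose expression patterns were to be compared. Median signal per array was 41.3 ± 1.24 (SD, n = 3) in control shoots, 37.2 ± 3.6 in potassium-starved shoots and 44.5 ± 1.33 in caesium-treated shoots. In roots it was 43.0 ± 0.333 in controls, 41.9 ± 2.23 under potassium starvation and 44.3 ± 0.75 under caesium. Arrays of 1 group correlated at r = 0.918 or higher across probe sets, and shoot with root arrays at 0.377 to 0.561. The first principal component held 49.3% of the variance among shoot arrays, where the potassium-starved arrays lay at positive scores and the other 6 at negative scores. Every group below has n = 3 arrays.

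Tissue genes separated control roots from control shoots. The light-harvesting gene LHCB4.1 had a signal of 3555 ± 108 in control shoots and 55.6 ± 10.9 in control roots, and RCA, which encodes Rubisco activase, 3352 ± 391 and 66.6 ± 41.3. The beta-glucosidase PYK10, abundant in roots, had 2351 ± 454 in control roots and 550 ± 565 in control shoots, and the root hair expansin EXPA7 66.5 ± 3.78 and 20.5 ± 5.69. By limma 5021 probe sets were higher and 3685 lower in control roots than in control shoots, of 16397 tested, and all 4 genes above were among them.

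Potassium starvation gave the most calls in shoots. Among called probe sets with 1 named gene, AMY1 (AT4G25000), an alpha-amylase, rose 27.0-fold from 29.3 ± 4.07 to 825 ± 328 (log2 4.75, adjusted p = 2.0e-05) and CML41, a calmodulin-like protein, 30.1-fold. SAG29 (AT5G13170), a senescence-associated gene of the SWEET sugar transporter family, rose from 7.45 ± 2.21 to 327 ± 107 (log2 5.45 ± 0.596 SE, adjusted p = 0.000326). AT3G13610, which encodes the feruloyl-CoA hydroxylase of coumarin synthesis, rose from 12.9 to 291 ± 61.5. AT1G31920 fell from 57.9 ± 24.4 to 3.28 ± 2.77, the transcription factor gene BZIP61 fell to 8.38 and AT1G12460 to 4.04. In these last 5, and in 16 of the 46 called genes named for this comparison, all 3 signals of the lower group lay below the 40th percentile of their arrays, so the size and rank of the difference are uncertain. With the pseudocount all 16 stayed called, and the log2 difference was 3.83 for SAG29 and 3.46 for AT3G13610, against 4.15 for AMY1 and 4.39 for CML41. It was -1.89 for AT1G31920, -2.53 for BZIP61 and -1.66 for AT1G12460.

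Further large rises in potassium-starved shoots, as log2 differences, were AT3G61930 (5.03 ± 1.03 SE), AT2G42350 (4.75 ± 1.04), AT2G32190 (4.71 ± 0.645), AT3G02480 (4.60 ± 1.13), SAL2 (4.60 ± 0.631) and AT4G18280 (4.55 ± 0.217). Further large falls were AT3G15570 (-3.83 ± 0.789), AT1G60990 (-3.68 ± 1.04), AT5G62280 (-3.65 ± 0.9), SWEETIE (-3.30 ± 0.563), AT5G07870 (-3.14 ± 0.807), AT2G25420 (-3.13 ± 0.426) and the plastid gene ndhH (-3.09 ± 0.646). Each of these 13 passed the test, with adjusted p from 8.3e-06 for AT4G18280 to 0.0244 for AT1G60990.

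Members of the lists fixed in advance changed in many directions in potassium-starved shoots. Of 59 tested members, 17 rose and 11 fell, against 18 and 14 adjusted over the list alone. Among abscisic acid, drought and cold genes 4 of 5 rose, namely LEA4-5 (3.62 ± 0.655), the dehydrin gene LTI30 (3.38 ± 0.496), COR15A (2.01 ± 0.658) and COR47 (0.69 ± 0.21), and COR15B fell (-1.02 ± 0.227). Among cyclic nucleotide-gated channels and glutamate receptors 4 of 6 rose, GLR2.7 (2.37 ± 0.648), GLR2.8 (1.33 ± 0.407), GLR1.4 (1.19 ± 0.292) and ATGLR1.2 (0.83 ± 0.267), and GLR3.3 fell (-0.84 ± 0.226). Both tested senescence genes rose, SAG29 and the transcription factor gene WRKY6 (2.31 ± 0.384). Both tested salicylate and defence genes rose, WRKY53 (1.57 ± 0.427) and SAG101 (0.94 ± 0.297). Only 70 of the 562 members of the fixed lists had a named probe set, so these counts do not describe whole pathways.

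Photosynthesis genes fell in 3 of 6 cases, LHCB4.2 (-0.95 ± 0.295), PRK, the phosphoribulokinase gene (-0.95 ± 0.284), and LHCB4.1 (-0.54 ± 0.146), where 4 of 6 fell adjusted over the list alone and only 1 of 6 passed after each array was shifted to a common median. The external NADH dehydrogenase gene NDB2 (2.53 ± 0.236) and the glutathione transferase gene GSTU25 (1.8 ± 0.303) rose among 3 oxidative stress genes. In the auxin list IAA29 (-2.52 ± 0.256) and HAT2 (-0.99 ± 0.212) fell among 5. Single called members of other lists were THI2.1 of the jasmonate list (2.35 ± 0.708), the zinc finger gene STZ (1.4 ± 0.372), EIN3 of the ethylene pathway (-0.69 ± 0.171), the replication gene PRL (-1.14 ± 0.198) and bHLH121 (-0.85 ± 0.231). In the sugar and starch list AMY1 rose and DPE1 fell (-1.34 ± 0.294). AT1G60160, the only member of the potassium transporter and channel list tested under its name, differed by -0.57 ± 0.31 and was not called (adjusted p = 0.188). Other members of that list may be among the tested probe sets that the annotation leaves unnamed. Of 3 sulphate, 3 glucosinolate and 4 flavonoid genes none was called.

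No fixed list of 5 testable ones shifted as a whole against all other genes in potassium-starved shoots with camera, and the lowest adjusted p was 0.0727, for abscisic acid, drought and cold genes (0.356 with an estimated correlation). The unadjusted camera p was under 0.05 for that list (0.0145) and for photosynthesis (0.0333), and fry called 4 lists. Leaving out control shoot replicate 1 gave 3 called lists, and leaving out control shoot replicate 3 or caesium-treated shoot replicate 2 gave 1 each. In the auxin list the median (-0.02) lay far nearer to 0 than the mean (-0.60), and the test pointed lower as well. The medians below stand against a median of -0.14 over all tested probe sets, which a shift to common array medians moved to 0.01.

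Among the gene families added later, IQ-domain proteins, which bind calmodulin, fell in 7 of 8 cases in potassium-starved shoots, with a median of -1.14. Autophagy genes rose in 4 of 8 cases, all of the ATG8 group, led by ATG8D (1.46) and ATG8B (1.42), with a family median of 0.67. Plastid-encoded genes fell in 19 of 68 cases (median -0.63), among them psaA of photosystem I (-2.28) and atpF of the plastid ATP synthase (-1.62), and in 10 of 68 after the median shift. Cytosolic ribosomal protein genes rose in 13 of 104 cases (median 0.22), a share near that of all probe sets (1670 of 14665). WRKY genes rose in 4 of 5 cases and WRKY20 fell, and the family's call was lost under quantile normalization (adjusted p = 0.0505) and under the median shift (0.0802). Camera adjusted p was 0.00895, 0.00518, 0.000351, 4.8e-05 and 0.0357 for these 5 families, and 0.44 for IQ-domain proteins and 0.606 for each of the other 4 with an estimated correlation, so no call held there.

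In all, limma called 1670 probe sets higher and 2446 lower in potassium-starved than in control shoots, of 14665 tested, and 966 of the higher and 1252 of the lower differed at least 2-fold. Of the tested probe sets 42.7% had no overlap between the groups, where chance gives 10%. The share of higher calls was 40.6%, 46.2% under quantile normalization (1837 higher, 2138 lower) and 53.3% after the median shift (2098 higher, 1836 lower). Both centre the arrays, which sets this balance, so the share is given as a value only. Without control shoot replicate 1 the count of calls was 2490, and without control shoot replicate 3 it was 2358.

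**Figure D1:**
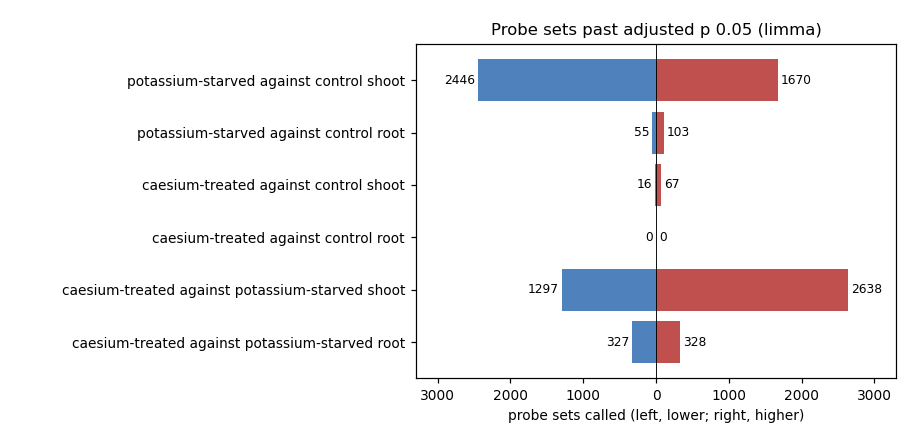
Number of probe sets called higher (right) and lower (left) by limma at an adjusted p under 0.05 in each of the 6 treatment comparisons, with 3 arrays per group. Potassium-starved against control shoots had 1670 higher and 2446 lower, and caesium-treated against control roots 0 and 0.

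Roots responded to potassium starvation in far fewer probe sets. AT3G12900, which encodes the scopoletin hydroxylase of coumarin synthesis, rose 7.15-fold, from 139 ± 39.8 to 965 ± 36.7 (log2 2.84 ± 0.196 SE, adjusted p = 0.000244). ASPGB1 (AT3G16150), an asparaginase gene, rose 3.58-fold from 179 ± 49.9 to 636 ± 137, and AT3G61930 4.03-fold from 80.0 ± 8.19 to 329 ± 85.5. AT1G73600, a phosphoethanolamine methyltransferase gene, fell 3.09-fold from 227 ± 56.2 to 72.6 ± 10.8, and AT5G19800 fell from 41.5 ± 2.01 to 6.17 ± 0.981. The lower group lay wholly below the 40th percentile for AT5G19800 and for 7 of 20 called named genes in all, so the size is uncertain. Each stayed called with the pseudocount, at log2 -1.38 for AT5G19800.

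The other large rises in potassium-starved roots, as log2 differences, were the small heat shock gene AT1G53540 (2.26 ± 0.356), AT2G41730 (2.14 ± 0.39), NAMT1 (1.91 ± 0.308), the germin-like gene AT5G38910 (1.89 ± 0.358), AT4G33666 (1.73 ± 0.181), AT4G22610 (1.71 ± 0.247) and AT5G66650 (1.53 ± 0.237). The other large falls were AT2G43600 (-2.38 ± 0.471), AT1G10810 (-2.14 ± 0.358), AT5G02890 (-2.0 ± 0.336), AT1G14960 (-1.74 ± 0.224), AT3G57010 (-1.70 ± 0.315), AT2G19060 (-1.63 ± 0.277), AT5G62360 (-1.58 ± 0.313) and AT3G05900 (-1.42 ± 0.203). Each passed the test, with adjusted p from 0.00574 for AT4G33666 to 0.0415 for AT2G43600.

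Of 48 tested members of the fixed lists, AT1G53540 of the heat shock list was the only one that rose in potassium-starved roots and none fell. Adjusted over the list alone 4 rose and 2 fell. These included both tested iron deficiency genes, PYE (0.64 ± 0.148, adjusted p over all probe sets 0.0672) and BHLH101 (1.21 ± 0.489, 0.226). Values not called over all probe sets included WRKY53 (-0.91 ± 0.235, adjusted p = 0.0912), the root hair expansin EXPA18 (-0.63 ± 0.183, 0.117), LHCB4.1 (0.62 ± 0.236, 0.205) and bHLH121 (0.36 ± 0.195, 0.355). Camera called neither of the 2 testable lists (adjusted p = 0.22 for photosynthesis and 0.493 for the channel and receptor list, which held glutamate receptors only). Fry called none, and neither unadjusted camera p was under 0.05. Leaving out potassium-starved root replicate 1 or control root replicate 3 gave 1 called list each.

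Among added families, trichome birefringence-like proteins, xyloglucan endotransglucosylases and IQ-domain proteins lay lower in potassium-starved roots, with medians of -0.49, -0.65 and -0.59 against -0.03 over all probe sets. TBL41 (-1.39) and XTH19 (-1.26) fell, and no IQ-domain gene was called. Of 6 defensin-like genes 3 rose, PDF2.1 (1.41), PDF1.4 (1.21) and LCR69 (0.86), and the family was not called (adjusted p = 0.0732). Cytosolic ribosomal protein genes lay lower, with a median of -0.30 and 1 of 102 called, and plastid-encoded genes higher, with a median of 0.32 and 0 of 57 called. Camera adjusted p was 8.1e-05, 0.0112, 0.000808, 1.6e-08 and 0.0178 for the trichome, xyloglucan, IQ-domain, ribosomal and plastid families. None of these calls held with an estimated correlation, where adjusted p was 0.342, 0.342, 0.422, 0.715 and 0.861. Of 185 shoot-specific probe sets outside the photosynthesis list, 138 were higher in potassium-starved than in control roots. They were picked for a high signal in control shoots and a far lower one on the same control root arrays. That choice by itself favours higher signals in any other roots. The actin 3'/5' ratio, a sign of RNA quality, was 5.61, 5.54 and 3.95 on potassium-starved and 7.19, 5.41 and 5.74 on control root arrays of replicates 1, 2 and 3.

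In all, 103 probe sets were higher and 55 lower in potassium-starved than in control roots by limma, of 14432 tested, and 77 and 33 differed at least 2-fold. The count of 158 was 87 without control root replicate 1, 28 without potassium-starved root replicate 3 and 38 without potassium-starved root replicate 2. It was 105 without the filter, 1076 with array weights, 71 when only these 6 arrays shared the spread and 76 with all 18 arrays in 1 fit.

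Shoot and root calls under potassium starvation overlapped. Of 12828 probe sets tested in both tissues, 49 were higher in both, where independent lists of these sizes would share 10.1, and 18 were lower in both, against 4.65. They included AT3G61930, AT3G13610 (0.96 in roots), AT2G28710 (3.16 in shoots and 1.41 in roots), the osmotin gene OSM34 (2.21 and 0.79), SRC2 (2.47 and 1.02) and WRKY22 (0.90 and 1.42), examples chosen after their values were seen. XTH19 was among 7 probe sets called in opposite directions, at 2.33 in shoots and -1.26 in roots. Across those probe sets the log2 differences correlated at r = 0.388, and genes are not independent replicates. The interaction test called 1373 probe sets, 699 with a response higher in roots and 674 with one lower, and 915 and 862 in all without potassium-starved root replicates 1 and 3. After the median shift 531 were higher and 781 lower.

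Caesium changed fewer genes in shoots. WRKY6 rose 4.64-fold, from 23.0 ± 13.1 to 94.9 ± 11 (log2 2.21 ± 0.384 SE, adjusted p = 0.0429), and CYP71B23, a cytochrome P450 gene, 3.09-fold from 97.9 ± 15.2 to 303 ± 48.8 (adjusted p = 0.0185). UGT73B5, a glycosyltransferase gene, rose from 5.8 ± 2.44 to 32.2 ± 2.7. The methionine sulfoxide reductase gene MSRB6 fell 4.05-fold, from 206 ± 34.8 to 51.4 ± 13.2, and the auxin-regulated gene IAA29 2.94-fold, from 159 ± 44.6 to 53.7 ± 12.7.

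Other large rises in caesium-treated shoots, as log2 differences, were AT1G65690 (2.46 ± 0.428), AT5G12930 (2.39 ± 0.397), AT1G26380 (2.28 ± 0.325), AT1G43910 (1.89 ± 0.227), AT3G13950 (1.70 ± 0.289), AT1G13340 (1.67 ± 0.315) and AT1G28190 (1.66 ± 0.252). Other falls were AT1G22330 (-1.64 ± 0.307), AT5G03120 (-1.56 ± 0.278), AT3G42800 (-1.36 ± 0.228), AT2G43550 (-1.26 ± 0.228), HAT2 (-1.18 ± 0.212) and AT3G50685 (-0.78 ± 0.144). The second probe set of AT1G22330 differed by -1.08 and was not called (adjusted p = 0.555). Adjusted p for these 13 ran from 0.0185 for AT1G43910 to 0.0495 for AT1G22330. The lower group lay wholly below the 40th percentile of its arrays for UGT73B5, AT5G12930, AT1G22330 and AT3G42800, 4 of 18 called named genes. Each stayed called with the pseudocount, at log2 1.15, 1.15, -1.03 and -0.94.

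Of 59 tested list members, WRKY6 rose and IAA29 and HAT2 fell in caesium-treated shoots, and adjusted over the list alone 9 rose and 5 fell. Values outside the threshold over all probe sets included NDB2 (1.24 ± 0.236, adjusted p = 0.0502), COR15B (-1.09 ± 0.227, 0.0605), AMY1 (1.18 ± 0.275, 0.0792), GSTU25 (1.26 ± 0.303, 0.0863) and PSAN of photosystem I (-0.54 ± 0.14, 0.104). With the pseudocount NDB2 passed in limma (adjusted p = 0.0461) and the others did not. Camera called 2 of 5 fixed lists lower. Photosynthesis genes had a median of -0.32 with 0 of 6 called (1 of 6 fell adjusted over the list alone), and camera gave an adjusted p of 0.00511, or 0.266 with an estimated correlation. Abscisic acid, drought and cold genes had a median of -0.76 with 0 of 5 called (2 of 5 fell adjusted over the list alone), and an adjusted p of 0.0394, or 0.266 with an estimated correlation. Quantile normalization ended both calls, fry called only the auxin list, and with the replicate block photosynthesis was called (adjusted p = 0.00517) and the abscisic acid list was not (0.0533). A single list was called without control shoot replicate 1 or 3 or caesium-treated shoot replicate 2. The same held without potassium-starved shoot replicate 1, 2 or 3, where fewer than 5 abscisic acid, drought and cold genes were left to test. Of the added families RALF-like peptides lay lower, with a median of -0.61 and 0 of 6 called (adjusted p = 0.0066, 0.501 with an estimated correlation, and 0.0667 after the median shift). With 1 array left out the count of called families ran from 1 to 6, the highest without control shoot replicate 2.

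In all, 67 probe sets were higher and 16 lower in caesium-treated than in control shoots by limma, of 14665 tested, and 65 and 14 differed at least 2-fold. With the paired replicate number as a block the count rose from 83 to 681, with 436 higher and 245 lower, and the higher share of 80.7% became 65.0% after the median shift (13 higher, 7 lower). The count was 34 without the filter, 144 with the stricter one, 159 with the pseudocount, 38 without the variance trend, 1196 with array weights, 49 when only 6 arrays shared the spread and 480 with all 18 arrays. It was 0 without control shoot replicate 3 or caesium-treated shoot replicate 3, 4 without caesium-treated shoot replicate 2, 10 without caesium-treated shoot replicate 1, 42 and 35 without potassium-starved shoot replicates 1 and 3, and 159 without potassium-starved shoot replicate 2.

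**Figure D2:**
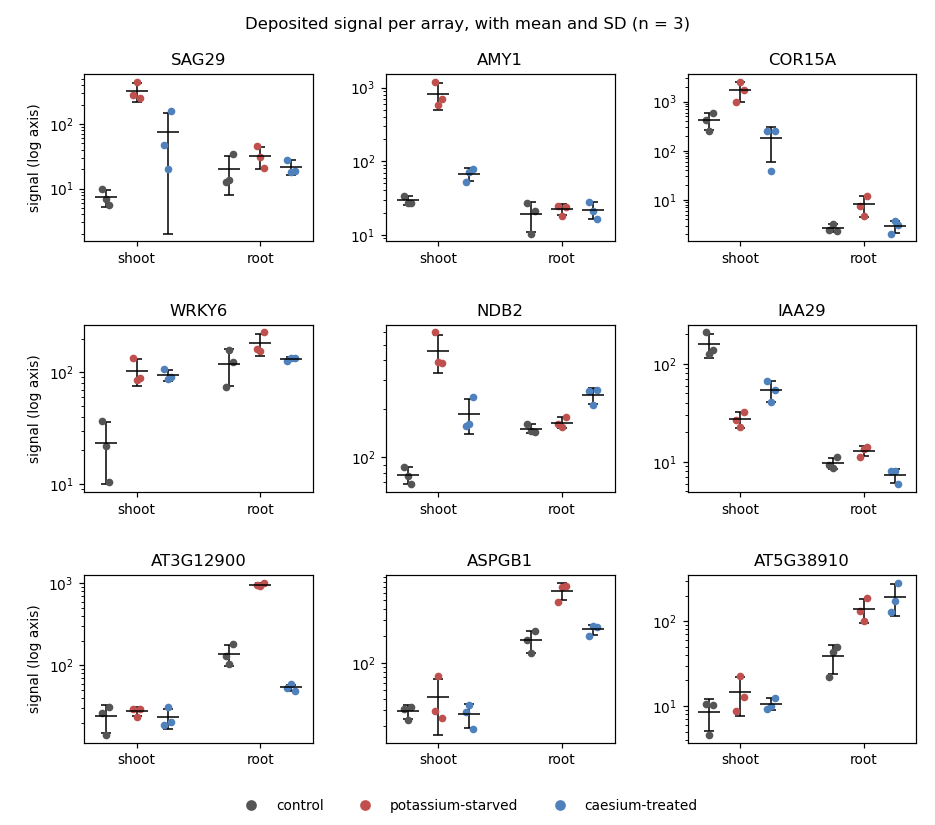
Deposited signal (log axis) of 9 named genes on each array, as points, with the group mean as a bar and the SD as whiskers (n = 3), in control, potassium-starved and caesium-treated shoots and roots. AMY1 stood at 825 ± 328 in potassium-starved and 29.3 ± 4.07 in control shoots, and AT3G12900 at 965 ± 36.7 in potassium-starved and 139 ± 39.8 in control roots.

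In caesium-treated roots limma called 0 probe sets against control roots, with 1399 at an unadjusted p under 0.05 where 722 would be expected by chance. The smallest adjusted p was 0.0733. The genes with the smallest p are given as values. AT5G38910 differed by 2.34 ± 0.358 (193 ± 79 against 38.3 ± 14.3), the lipid transfer protein gene AT4G12490 by 2.17 ± 0.356, AT1G78780 by 1.74 ± 0.263, the defensin genes PDF1.4 and PDF2.1 by 1.18 ± 0.174 and 1.00 ± 0.162, and the plastid gene ndhC by 1.16 ± 0.194. AT5G19700 differed by -2.08 ± 0.321, AT3G12900 by -1.33 ± 0.196 (53.9 ± 4.65 against 139 ± 39.8), AT5G60760 by -1.17 ± 0.191 and AT5G48430 by -1.04 ± 0.164. Their adjusted p ran from 0.0733 to 0.0816.

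None of 48 tested list members was called in caesium-treated roots. Adjusted over the list alone, with no adjustment across lists, 7 passed as higher and 3 as lower. BCAT4 of glucosinolate synthesis differed by -1.0 ± 0.179 (adjusted p = 0.104), NDB2 by 0.68 ± 0.148 (0.167), AT2G21640 by 1.14 ± 0.293 (0.227), LBD29 of the auxin list by -0.83 ± 0.229 (0.258) and COR47 by -0.61 ± 0.183 (0.298). Photosynthesis genes lay higher as a list by camera, with a median of 0.87 and an adjusted p of 3.9e-05, or 0.147 with an estimated correlation. LHCB4.1 stood at 103 ± 29.4 against 55.6 ± 10.9, and RCA at 147 ± 33 against 66.6 ± 41.3. None of the 5 tested members was called over all probe sets, and 4 of 5 rose adjusted over the list alone. The call was lost with fry. Without caesium-treated root replicate 1, caesium-treated root replicate 2 or potassium-starved root replicate 2 fewer than 5 members passed the filter, so the list was not tested and 0 lists were called. In the list of cyclic nucleotide-gated channels and glutamate receptors, which held receptors only, the median was 0.01, the mean -0.01 and the test's direction down (adjusted p = 0.934).

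Other shoot-specific transcripts were higher in the same roots. Of 185 shoot-specific probe sets outside the photosynthesis list, 164 were higher in caesium-treated than in control roots, and their median signal was 1.95%, 2.49% and 1.97% of that in control shoots on the 3 caesium-treated root arrays. On the 3 control root arrays it was 1.1%, 1.07% and 1.71%. The probe sets were picked for low signals on these control arrays, which by itself favours higher signals in other roots. Of them 87 passed the filter in roots. In caesium-treated against potassium-starved roots, which the choice did not use, 145 were higher. Among added families plastid-encoded genes (median 0.33), defensin-like proteins (0.48) and cytosolic ribosomal proteins (0.26) lay higher and trichome birefringence-like proteins (-0.23) lower, with 0 members called in each. Camera adjusted p was 0.00576, 0.000963, 1.0e-11 and 0.0227, and 0.834, 0.153, 0.815 and 0.771 with an estimated correlation. The count of 4 called families was 2 without control root replicate 1, control root replicate 2 or caesium-treated root replicate 2, and 6 without caesium-treated root replicate 1.

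The count of 0 was also 0 under quantile normalization, the median shift and both other filters. It was 1 with the pseudocount, 1 without the variance trend, 21 with array weights and 27 with all 18 arrays in 1 fit, 7 without control root replicate 2 and 1 without caesium-treated root replicate 2. With the replicate number as a block it was 42, with 20 higher and 22 lower, though the pairing in these roots was weakly shown.

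The responses of shoots to caesium and to potassium starvation shared calls. WRKY6 rose 4.64-fold and 4.97-fold, and IAA29 fell in both, with log2 differences of -1.56 and -2.52. Of 83 probe sets called under caesium, 55 were higher in both comparisons and 10 lower in both, where independent lists would share 7.63 and 2.67, 2 were called in opposite directions, and 74 of 83 had the same sign. Unchanged groups simulated against shared controls shared 0.01 calls on average, but such groups hold almost no calls, so this is no measure for lists that do. Independent lists leave out the shared controls, so the excess over either value cannot be taken as a shared effect, and its source stays open. Across 14665 probe sets r was 0.477, against 0.50 in that simulation, and the covariance of the log2 differences was 0.189 against 0.0631. The same-sign share was 58.0%, against 66.6% simulated. In roots r was 0.245, against 0.50, the covariance 0.0358 against 0.0400, and no call was shared because caesium gave none in the main fit. Unchanged groups of equal size with shared controls give an r near 0.50 by construction, and a response in either treatment moves r away from it. The simulated r and same-sign share are therefore no measure of likeness. The simulation drew arrays independently, so its covariance leaves out the pairing of arrays. Only 3 control arrays exist per tissue, too few for 2 sets of at least 2 arrays, so part of the excess may come from the shared controls.

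**Figure D3:**
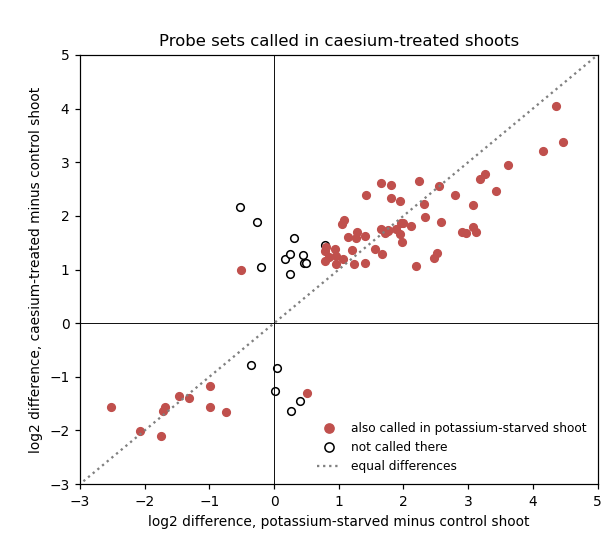
Log2 difference from control shoots of the 83 probe sets called in caesium-treated shoots, under potassium starvation (horizontal) and under caesium (vertical), 1 point per probe set. Filled points were also called in potassium-starved shoots, and the dotted line marks equal differences. Of the 83 points, 55 were called higher in both conditions and 10 lower in both.

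Caesium-treated and potassium-starved shoots were also compared with each other. AT4G18280 was 28.3-fold lower, at 52.4 ± 7.24 against 1497 ± 346 (log2 -4.82 ± 0.217 SE, adjusted p = 4.6e-06), AMY1 11.9-fold lower, at 67.1 ± 13.6 against 825 ± 328, and CML41 15.8-fold lower. AT1G31920 was higher, at 51.7 ± 11.6 against 3.28 ± 2.77, and so was NET1B, at 49.7 ± 13.1 against 3.02 ± 1.72. For these 2 genes, and for 12 of 32 called named genes in all, the lower group lay wholly below the 40th percentile of its arrays, so the size is uncertain. All 12 stayed called with the pseudocount, at log2 1.81 for AT1G31920 and 1.77 for NET1B.

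Other genes lower under caesium than under potassium starvation in shoots were AT1G58420 (-4.24 ± 0.223), AT5G45630 (-4.14 ± 0.459), SAL2 (-3.98 ± 0.631), AT2G42350 (-3.80 ± 1.04), AT1G21550 (-3.69 ± 0.315), COR15A (-3.59 ± 0.658) and AT1G16850 (-3.57 ± 0.731). Others that were higher were ndhH (3.90 ± 0.646), AT5G59670 (3.85 ± 1.12), AT2G25420 (3.49 ± 0.426), SWEETIE (3.27 ± 0.563), AT1G13730 (3.23 ± 0.299), AT3G15570 (3.07 ± 0.789), AT3G17740 (3.04 ± 0.6) and the topoisomerase gene TOPII (3.04 ± 0.633). All 15 were called, with adjusted p of 0.03 or lower.

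Of 59 tested list members, 6 were higher and 8 lower in caesium-treated than in potassium-starved shoots, against 9 and 8 adjusted over the list alone. Abscisic acid, drought and cold genes were lower in 4 of 5 cases, COR15A, LTI30 (-3.0 ± 0.496), LEA4-5 (-2.90 ± 0.655) and COR47 (-1.45 ± 0.21). Camera called this list (median -2.90, adjusted p = 0.000529), and not with an estimated correlation, where adjusted p was 0.209. With the stricter filter, and without any 1 of the 3 potassium-starved shoot arrays, fewer than 5 members passed the filter, so the list was not tested and 0 lists were called. NDB2 (-1.30 ± 0.236), SAG29 (-2.56 ± 0.596) and BCAT4 (-0.94 ± 0.311) were lower. EIN3 (0.90 ± 0.171), GLR3.3 (1.12 ± 0.226), bHLH121 (0.96 ± 0.231), IAA29 (0.96 ± 0.256), PRL (1.1 ± 0.198) and the sulfite reductase gene SIR (0.48 ± 0.155) were higher.

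Of the added families, 8 were called between these shoots, against a median of 0.16 over all probe sets, which the median shift moved to -0.11. IQ-domain proteins were higher in 7 of 8 cases (median 1.00, adjusted p = 0.036), but in 2 after the median shift, where 1 was lower, and in 3 after quantile normalization, where the family was no longer called. Plastid-encoded genes were higher in 22 of 68 cases and lower in 1 (median 0.47, 0.0192), and in 14 and 5 after the median shift. Cytochromes P450 were higher in 3 of 13 cases (0.67, 0.0387). Tetraspanins were lower in 2 of 9 cases (-0.26, 0.0229), ubiquitin-conjugating enzymes in 4 of 11 (-0.52, 0.0192), autophagy genes in 2 of 8 (-0.60, 0.0192) and RALF-like peptides in 3 of 6 (-0.72, 0.0192, not called after the median shift). Cytosolic ribosomal proteins were lower in 8 of 104 cases and higher in 3 (-0.15, 0.00169), and their median turned to 0.02 under quantile normalization. Of all 14665 probe sets 1297 were lower and 2638 higher, so the lower share of this family was near that of all. With an estimated correlation no family was called, and the lowest adjusted p was 0.396. The count of 8 families was 0 without potassium-starved shoot replicate 2, 5 without potassium-starved shoot replicate 1 or 3, and 7 to 9 without each of the other arrays.

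In all, 2638 probe sets were higher and 1297 lower in caesium-treated than in potassium-starved shoots by limma, of 14665 tested, and 1402 and 559 differed at least 2-fold. The share of higher calls was 67.0%, 55.4% after quantile normalization (2014 higher, 1619 lower) and 39.5% after the median shift (1524 higher, 2331 lower), where the centring sets the balance. The count of 3935 was 1894 without caesium-treated shoot replicate 1, 2456 without caesium-treated shoot replicate 2, 2229 without caesium-treated shoot replicate 3 and 2295 without potassium-starved shoot replicate 2.

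In roots AT3G12900 was 17.9-fold lower under caesium than under potassium starvation, at 53.9 ± 4.65 against 965 ± 36.7 (log2 -4.16 ± 0.196 SE, adjusted p = 4.1e-06). AT3G61930 was 8.88-fold lower, at 36.4 ± 4.78 against 329 ± 85.5, and AT3G58060, which encodes the manganese transporter MTP8, lower as well, at 18.8 ± 3.41 against 80.1 ± 22.4. The lower group lay wholly below the 40th percentile for AT3G58060 and for 10 of 23 called named genes in all, so the size is uncertain. Each stayed called with the pseudocount, at log2 -1.44 for AT3G58060. The beta-glucosidase gene BGLU25 was 4.52-fold higher, at 763 ± 262 against 175 ± 89.2, and AT5G10130 4.16-fold higher, at 302 ± 41.2 against 72.9 ± 12.7.

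Other genes lower under caesium in roots were AT5G19700 (-3.45 ± 0.321), AT1G73120 (-3.02 ± 0.332), AT5G59080 (-2.35 ± 0.412), AT5G48430 (-2.08 ± 0.164), AT3G07720 (-2.04 ± 0.245), AT2G28710 (-2.01 ± 0.195) and AT1G53540 (-2.01 ± 0.356). Others that were higher were AT5G22580 (2.99 ± 0.601), AT2G43600 (2.94 ± 0.471), AT1G61080 (2.74 ± 0.657), AT1G74490 (2.5 ± 0.435), AT5G19800 (2.48 ± 0.347), AT1G10810 (2.33 ± 0.358), AT4G12490 (2.15 ± 0.356) and AT5G14650 (2.00 ± 0.455). All 15 were called, with adjusted p of 0.0419 or lower.

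Of 48 tested list members, GSTU25 was higher (1.94 ± 0.455) and PYE (-0.74 ± 0.148), BCAT4 (-1.35 ± 0.179) and AT1G53540 were lower in caesium-treated than in potassium-starved roots. Adjusted over the list alone 6 were higher and 6 lower. Fry called none of the fixed lists. Camera called 0 of 2 testable ones (adjusted p = 0.102 for photosynthesis and 0.492 for the channel and receptor list, which held glutamate receptors only), with neither unadjusted p under 0.05. It called photosynthesis without the filter, with array weights and with all 18 arrays in 1 fit, and without control root replicate 1 or 3. Of 185 shoot-specific probe sets outside that list, 145 were higher in caesium-treated than in potassium-starved roots. Cytosolic ribosomal protein genes were higher in 17 of 102 cases (69 of 102 adjusted over the list alone) and lower in none, with a median of 0.55 against 0.04 over all probe sets. The actin 3'/5' ratio, a sign of RNA quality, was 8.15, 5.45 and 6.67 on caesium-treated and 5.61, 5.54 and 3.95 on potassium-starved root arrays, in the order of replicates 1, 2 and 3. Camera gave an adjusted p of 9.1e-22 for this family and 0.764 with an estimated correlation. Autophagy genes lay lower with a median of -0.29 and 1 of 8 called (adjusted p = 0.0243, 0.764 with an estimated correlation, and 0.0605 after quantile normalization). Without caesium-treated root replicate 1 or potassium-starved root replicate 2, 1 family was called in place of 2.

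In all, 328 probe sets were higher and 327 lower in caesium-treated than in potassium-starved roots by limma, of 14432 tested, and 165 and 156 differed at least 2-fold. The share of higher calls of 50.1% became 35.7% after the median shift, with 252 higher and 454 lower. The count of 655 was 128 without caesium-treated root replicate 1, 175 without caesium-treated root replicate 3, 126 without potassium-starved root replicate 2 and 150 without potassium-starved root replicate 3, and 2548 with array weights.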

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

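The tests of scaling, array pairs and shoot transcripts below were set before their results were seen, and the family of cytosolic ribosomal proteins was chosen after the annotation had been seen and before any difference between groups had been computed. Both root patterns, the check of low signals and the test of 1 pair as the whole cause were picked after their values were seen, and the regrouping within replicate numbers after the free regroupings. The difference between the responses of roots and shoots was tested itself, as an interaction, and it passed the threshold for 1373 probe sets under potassium starvation and 23 under caesium. This difference between tissues is why the genes of the next 2 paragraphs are named, and the last 2 paragraphs weigh patterns within roots.

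IAA29 had log2 differences of -2.52 in potassium-starved shoots and 0.41 in roots, so the root response was higher by 2.93 (adjusted p = 0.000208). PORB, a protochlorophyllide oxidoreductase gene of chlorophyll synthesis, had -1.63 in shoots and 1.04 in roots, a difference of 2.67. Its signals were 1942 to 2014 in control shoots, 13.0 to 15.9 in control roots and 22.5 to 35.9 in potassium-starved roots. There 138 of 185 shoot-specific probe sets, picked for low control root signals, were higher than in control roots. AT2G16660 had -2.02 and 1.15 (difference 3.16), AT4G33666 -0.63 and 1.73 (2.36) and AT3G11930 -1.0 and 0.80 (1.8). In the other direction AT4G18280 had 4.55 in shoots and 0.39 in roots, a difference of -4.16 (adjusted p = 2.1e-06). AT1G58420 had 4.16 and 0.21 (-3.95), AT5G37540 3.11 and -0.72 (-3.83), AT1G55210 3.18 and -0.45 (-3.63) and AT1G67360 2.01 and -0.32 (-2.34). All 10 kept the call with the pseudocount, but at least 1 group lay wholly below the 40th percentile of its arrays for 4 of them, so the size is uncertain there. With the pseudocount the difference was 2.16 for IAA29 (both root groups below), 2.2 for PORB, -3.55 for AT1G58420 and -3.02 for AT5G37540. The count of 1373 was 915 without potassium-starved root replicate 1 and 862 without potassium-starved root replicate 3. Of 100 regroupings within tissue, 8 gave at least as many calls, the real one included, and the highest other gave 4084. The 7 others all kept the real shoot labels, so they still held the shoot response and say little about chance. Regroupings that mixed the shoot labels reached at most 42. These regroupings ignore the pairing of the shoot arrays.

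Under caesium several differences rest on signals near the floor. The light-harvesting gene LHCB4.2 had -0.55 in shoots and 3.33 in roots, a difference of 3.88 (adjusted p = 0.0276), at root signals of 2.45 ± 1.54 in controls and 22.3 ± 5.78 under caesium (n = 3). AT1G23130 had -0.18 and 5.12 (5.30), AT1G67860 -0.01 and 3.63 (difference 3.63), NOL, a chlorophyll b reductase gene, -0.39 and 1.5 (1.89), and AT4G33666 -0.94 and 0.63 (1.57). In the other direction AT3G17110 had 2.82 in shoots and -0.36 in roots (-3.18), AT2G25450 0.70 and -1.48 (-2.19), AT2G28710 1.14 and -0.60 (-1.74) and AT4G01870 1.52 and -0.16 (-1.68). Control root signals were 0.424 to 0.720 for AT1G23130, 1.47 to 4.23 for LHCB4.2, 1.2 to 2.1 for AT1G67860 and 0.937 to 1.22 for NOL, and control shoot signals 1.29 to 3.77 for AT3G17110, far below the 40th percentile of those arrays (25.9 to 27.6). With the pseudocount these 5 lost the call, at 1.42, 1.59, 1.02, 0.49 and -1.06 (adjusted p = 0.357, 0.0638, 0.313, 0.247 and 0.107), so they are not given as tissue-specific responses. AT4G33666, AT2G25450, AT2G28710 and AT4G01870 kept it. For AT2G28710 all 3 control shoot signals (20.93 to 26.86) also lay below the 40th percentile of their arrays. Each of the 9 named genes lost the call in at least 1 setting other than a left-out array. The count of 23 was 0 without caesium-treated shoot replicate 2 or 3, 12 without caesium-treated shoot replicate 1, and 4, 3 and 11 without caesium-treated root replicates 1, 2 and 3. It was 52, 43 and 12 without control shoot replicates 1, 2 and 3, and 5 and 14 without control root replicates 1 and 2. It was 14 and 59 without potassium-starved shoot replicates 1 and 2, and 41 and 10 without potassium-starved root replicates 2 and 3. Of 100 free regroupings within tissue, which ignore the pairing of the arrays, 4 gave at least as many calls, the real one included, and the highest other gave 62. When caesium-treated and control arrays were exchanged only within replicate numbers, 3 of 32 did so, the real one included (highest other 278), so chance was not excluded. The others that passed the real count all kept the real shoot labels, and regroupings that mixed these reached at most 10 and 3.

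Photosynthesis genes lay higher in caesium-treated than in control roots, with a median of 0.87 over 5 genes. Scaling was argued against as the whole cause, since the median stayed at 0.823 or higher under both other scalings. A carry-over of shoot tissue or RNA stays open. Over 185 other shoot-specific probe sets the measured gain was 0.566 of that predicted from the photosynthesis genes (95% bootstrap interval 0.489 to 0.681). The interval resampled probe sets and not arrays, so it leaves out the spread between arrays. Of the 185, 164 were higher, but they were picked for low control root signals, which favours such a gain. The pairs of same-numbered arrays gave 0.972, 1.56 and 0.171. The test of pairs set in advance was undecided, since not every pair held the rise. Judged after these values were seen, pairs 1 and 2 argue against 1 pair as the whole cause. The 25S ribosomal RNA control probe had 2862, 2188 and 212 on the caesium-treated and 261, 848 and 278 on the control arrays of replicates 1, 2 and 3. A difference in RNA quality, or a change in the roots under caesium, which the design names, may also be the source, and neither was tested.

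Cytosolic ribosomal protein genes lay lower in potassium-starved and higher in caesium-treated roots, with 8 and 96 of 102 genes above 0. Between the treatments the median was 0.552, where the highest of 10000 random lists matched on signal reached 0.167, which argues against a trend shared by bright probe sets. Scaling left 0.470 or more, and the pairs gave 0.906, 0.172 and 0.613, which argues against scaling and a single pair as the whole cause of this difference between the treatments. Against control the pairs gave 0.381, -0.0773 and 0.443 under caesium and -0.539, -0.169 and -0.182 under potassium starvation, so the rise under caesium was not in every pair. RNA quality and an effect of the treatments both stay open and untested: the actin 3'/5' ratio was 8.15, 5.45 and 6.67 under caesium, 5.61, 5.54 and 3.95 under potassium starvation and 7.19, 5.41 and 5.74 in controls, apart in the same pairs, and the family was not called with an estimated correlation (adjusted p = 0.764).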

How the results depend on the processing

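The added gene families were chosen after the annotation of the deposited table had been seen and before any difference between groups had been computed. The calls in potassium-starved against control shoots, between caesium-treated and potassium-starved shoots, in the interaction under potassium starvation and between control tissues stayed within 1.5 times their counts in every setting other than leaving out an array. No called named gene changed direction, but after the median shift, which by itself moves the balance of higher and lower, the share of higher calls went from 40.6% to 53.3% in potassium-starved against control shoots and from 67.0% to 39.5% between treated shoots. The cause of the differences below was not tested, except that filters and left-out arrays change how many genes or arrays are used.

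In caesium-treated against control shoots the 83 calls became 34 without the filter, 144 with the stricter filter, 159 with the pseudocount, 20 after the median shift, 38 without the variance trend, 1196 with array weights, 681 with the replicate block, 49 with only the 6 arrays compared and 480 with all 18 arrays in 1 fit. In potassium-starved against control roots the 158 became 105 without the filter, 1076 with array weights, 735 with the block, 71 with only 6 arrays and 76 with all 18. In caesium-treated against control roots the 0 became 1 with the pseudocount, 1 without the variance trend, 21 with array weights, 42 with the block and 27 with all 18 arrays. Between caesium-treated and potassium-starved roots the 655 became 2548 with array weights and 1574 with the block. The interaction under caesium (23) became 37 with the stricter filter, 35 after the median shift, 10 without the variance trend, 237 with array weights and 66 with the block.

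Called gene lists in potassium-starved against control shoots (0) became 4 with fry, 1 with the stricter filter and 1 under quantile normalization. In caesium-treated against control shoots (2) they became 0 with an estimated correlation, 1 with fry, 1 with the stricter filter, 0 under quantile normalization, 1 after the median shift, 1 without the variance trend and 1 with the block. Between caesium-treated and potassium-starved shoots (1) they became 0 with an estimated correlation and 0 with the stricter filter. In caesium-treated against control roots (1) they became 0 with an estimated correlation, 0 with fry, 2 without the filter and 2 with all 18 arrays. Between those treatments in roots (0) they became 1 without the filter, 1 with array weights and 2 with all 18 arrays. The stricter filter left fewer than 5 tested members in every list in roots, so it gave no value there.

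With 1 array left out, calls ran from 2358 to 3930 in potassium-starved against control shoots, 0 to 159 in caesium-treated against control shoots, 1894 to 3869 between caesium-treated and potassium-starved shoots, 28 to 218 in potassium-starved against control roots, 0 to 7 in caesium-treated against control roots, 126 to 702 between caesium-treated and potassium-starved roots, 862 to 1894 in the interaction under potassium starvation, 0 to 59 in that under caesium and 7857 to 9088 between control tissues. Called lists ran, in the first 6 of these, from 0 to 3, 1 to 2, 0 to 1, 0 to 1, 0 to 1 and 0 to 1. The covariance beyond shared controls ran from 0.0629 to 0.183 in shoots and -0.0222 to 0.0315 in roots.

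Of the called named genes, 260 of 260 checks under other settings kept the call for the interaction under potassium starvation, 747 of 835 for potassium-starved against control shoots, 546 of 579 between treated shoots, 371 of 415 between treated roots, 297 of 364 for potassium-starved roots, 166 of 331 for caesium-treated shoots and 140 of 233 for the interaction under caesium, and 0 reversed. Same-numbered arrays correlated at -0.0506 to 0.506 in potassium-starved against control roots, where other pairs reached 0.432, and at 0.0922 to 0.292 between treated roots, where other pairs reached 0.163. With at least 1 pair under the limit of 0.1 these 2 comparisons were not taken as paired, though a partial pairing stays open. The replicate block moved no count other than those given by over 1.5 times. Across comparisons it ended 0 calls of named genes and added 30.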

Other observations

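The test of scaling as a source of the lean to lower calls in potassium-starved shoots was chosen after the lean was seen, and the splits and free regroupings of the arrays were set before their results were seen. The regrouping within replicate numbers was added after the free regroupings had been seen.

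Transcripts of PYK10 and the defensin gene PDF1.2, picked after their values were seen, differed widely between replicate numbers in shoots, with the highest signals in replicate 2 of every group. PYK10 signal in control, potassium-starved and caesium-treated shoots was 173, 46.9 and 129 in replicate 1, 1199.7, 903 and 949 in replicate 2 and 279, 521 and 420.0 in replicate 3. PDF1.2 signal was 247, 51.5 and 425 in replicate 1, 2008, 1692 and 2462 in replicate 2 and 33.2, 41.4 and 207 in replicate 3. In roots PYK10 ran from 1915 to 3501.

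In potassium-starved shoots 40.6% of calls were higher. The share was 46.2% under quantile normalization and 53.3% after the median shift, but both centre the arrays and thereby set this balance, so they do not decide whether scaling is the source. Potassium-starved shoot replicate 2, the array with the lowest median signal (33.0), was argued against as the whole cause, since without it the share was 43.2%. Scaling and a change in total transcript amount under potassium starvation stay open.

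Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. These splits ignore the pairing by replicate number. Among the other splits that part all 3 pairs, the highest count of called probe sets was 0 in each comparison. The highest other counts of 113, 1 and 5 below came from splits that part only 1 pair. Splits with at least as many calls, the real one included, numbered 1 in potassium-starved against control shoots (4116 calls, highest other 0), 1 in potassium-starved against control roots (158, highest other 113), 1 in caesium-treated against control shoots (83, highest other 1) and 10 in caesium-treated against control roots (0, highest other 5). They numbered 1 between caesium-treated and potassium-starved shoots (3935, highest other 0), 1 between those roots (655, highest other 0) and 1 between control roots and shoots (8706, highest other 0). For called gene lists the numbers were 10 in potassium-starved against control shoots (0 lists, highest other 2), 10 in those roots (0, highest other 1), 2 in caesium-treated against control shoots (2, highest other 2) and 4 in those roots (1, highest other 1). Between caesium-treated and potassium-starved plants they were 6 in shoots (1, highest other 2) and 10 in roots (0, highest other 1).

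The covariance of the responses beyond the shared controls was 0.126 in shoots, which 13 of 100 free regroupings matched or passed, the real one included (highest other 0.497). It ran from 0.0629, without control shoot replicate 3, to 0.183 with 1 array left out. Free regroupings ignore the pairing of the shoot arrays. When the treatments were regrouped only within replicate numbers, 11 of 100 matched or passed it, the real one included (highest other 0.499, median of the others -0.0196). In roots the covariance was -0.00424, matched or passed by 37 of 100 free regroupings (highest other 0.107). Regroupings of either kind can label potassium-starved arrays as controls, and both differences then hold the response to starvation. They therefore cannot measure chance, which was not excluded.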
